A study of Mus musculus with 20 samples.

How the data were processed

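Poly(A) RNA of C57BL/6J mouse embryo and embryonic brain sections was sequenced after MAPIT-seq with anti-G3BP1 or rabbit IgG, a guinea pig anti-rabbit secondary antibody and the fusion rAPOBEC1-pAG-hADAR2, or without treatment. RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 kit, per the labels. Antibody libraries carry a fixation of 0.2% formaldehyde in the labels, and untreated libraries carry none. The titles of the untreated libraries of the fixed embryo nevertheless call them fixed. The 20 libraries were grouped by stage, tissue, preparation and antibody as the labels give them, in 10 groups of 2. No replicate was assumed to be paired with another.

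The 4 deposited editing tables hold, per the file headers, 2 count values per site and library: the reads covering the site and the reads with the edited base. In these counts a value of 1 is rarer than 2 in most libraries, so single edited reads seem to have often been set to 0 before deposition. The 4 deposited expression tables hold TPM by the authors, which sum to 1000000 in each library over the 27369, 34527, 34555 and 34555 genes listed. Per the submitters' processing notes, BWA 0.7.17, HISAT2 2.2.1, Picard 3.1.1, GATK 4.5.0.0, Subread and featureCounts 2.0.1 were used with the builds mm10 and GRCm38. The role and settings of each tool, the annotation and the rule for calling a site are not given in the sources used here. Each editing table holds its own set of sites. There were 92951 in the fixed embryo, 150516 in the fresh-frozen embryo, 263989 in E12.5 brain and 375414 in E16.5 brain. This was after 36, 104, 104 and 215 repeated lines were removed. In the same order, 1143, 1575, 213986 and 162708 sites had no edited read in any library of their table. Such sites were kept where depth allowed, so their reads count in the edited shares below. The reference base of each site was checked against the transcript sequences, which were the same at all sites with a transcript base. Gene, region and preceding base came from the mouse annotation.

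Sites with 10 or more reads in every library of their table were kept, and edited and unedited reads were summed per gene. Genes with 50 or more such reads in every library were tested with a quasi-binomial logistic model. Its Pearson dispersion was moderated with squeezeVar of limma 3.58.1 along a trend on edited reads and kept at 1 or more, after 0.25 edited and 0.25 unedited reads were added per library. Changes are log2 odds ratios of anti-G3BP1 over IgG. Differences between tables were tested as an interaction in the same model over sites present in both. The overall edited share was compared by an exact two-sided permutation of the antibody within the 4 tables. Expression was tested with limma (eBayes with trend) on log2(TPM + 1) for genes with 1 TPM or more in at least 2 libraries; for the 2 brain tables TPM was rescaled over shared genes and the antibody was a covariate. All p-values per gene are two-sided and adjusted by Benjamini-Hochberg, and genes at an adjusted p under 0.05 were called. Gene lists, 42 in all, were tested with cameraPR at a correlation of 0.01 and with camera at an estimated correlation where 5 or more genes were tested, adjusted over lists. A gain per list over all its sites, relative to other sites, was permuted within tables in the same way as the overall share. This measure, the shares per region and preceding base and the test of shared calls were added after the data were seen.

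The design with its tests, the lists, 22 alternatives and the rule for named genes were fixed before the data were examined. That rule takes, per editing comparison, the 10 higher and 10 lower genes with the largest change among those called with 200 or more reads in every library, a gene symbol and groups that do not overlap. Per expression comparison it takes the 10 higher and 10 lower called genes with the largest change, 10 TPM or more in the higher group and groups that do not overlap. Up to 4 members with the smallest p from each called list, and G3bp1, G3bp2 and Caprin1 in every comparison, are added. Of these genes the text prints a selection, and some are not reported here. Another 10 alternatives were added after the data were seen: sites with 1 alternative allele, sites listed under 1 gene, reads thinned to the shallowest library, dispersion moderated to 1 value, and all sites of each table for differences. The rest were lists against the median change, the overall share with thinned reads, without each table, or without the 100 sites with most edited reads, and the stage comparison without the first IgG libraries. The alternatives fixed in advance were other read minimums, each kind of edit alone, no sites edited in 50% of reads or more, and a test against the median change. They also held limma on the empirical logit with 0.5 added reads, the quasi-likelihood test of edgeR 4.0.16, a replicate block, another pseudocount, no filter, rescaling without mitochondrial and haemoglobin genes, quantile normalization, and leaving out each library in turn.

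Both tests were tested on simulated data with known changes. Edited reads were drawn in pairs at each gene's real depth and mean editing, without a general gain or further spread between replicates. Log2 TPM values were drawn around each gene's mean with its residual spread. The known changes were placed only on genes with more edited reads or a higher TPM. Intervals for a share are Wilson intervals at 95%, and a count of 0 is taken to allow up to 3 counts. Depth per library is given with the results, as mean reads per kept site; for TPM no counts per gene were used. Introns and sites outside exons were too few for a test of their own. Sequencing reads and the studied paper were not used here. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and data.table (1.17.8).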

Results

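RNA contacts of G3BP1, an RNA-binding protein that nucleates stress granules, were read by MAPIT-seq in sections of mouse embryos and embryonic brains. In this assay a primary antibody and a secondary antibody bring a protein A/G fusion of the cytidine deaminase rAPOBEC1 and the adenosine deaminase domain of human ADAR2 to the target. Nearby transcripts then carry C-to-T and A-to-G changes in poly(A) RNA sequencing. The 20 libraries formed 10 groups of 2. Sections labelled E10.5 fixed embryo and sections labelled E10.5 fresh-frozen embryo each gave IgG, anti-G3BP1 and untreated libraries, and E12.5 and E16.5 brain each gave IgG and anti-G3BP1 libraries. The IgG libraries are the background of the fusion without a specific antibody, and the untreated libraries are the background of sequencing and of endogenous editing. Edited sites and transcript levels came from the same libraries, in 4 separately deposited tables of each kind.

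Sites with 10 or more reads in every library of their table numbered 59070 in the fixed embryo, 104878 in the fresh-frozen embryo, 126802 in E12.5 brain and 337325 in E16.5 brain. Mean depth at these sites was 205 and 133 reads in the fixed IgG libraries, 119 and 93.5 in the anti-G3BP1 libraries, and 119 and 33.8 in the untreated libraries. In the fresh-frozen table it was 56.1 and 56.9 reads with IgG, 64.7 and 93.9 with anti-G3BP1, and 73.5 and 65.7 without treatment. E12.5 brain had 23.1 and 68.9 reads with IgG and 55.3 and 64.9 with anti-G3BP1, whereas E16.5 brain had 189.7 and 139 with IgG and 109 and 182 with anti-G3BP1. The median gene held 4, 5, 2 and 7 edited reads per library in the fixed, fresh-frozen, E12.5 and E16.5 tables, so single genes rested on few edited reads. Each library held between 17310 and 25508 genes at 1 TPM or more, and replicates correlated at Pearson r between 0.938 and 0.991 across genes on the log2 scale. The labels do not say that replicates are separate animals, so p-values measure only the spread between these samples, which may be technical.

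The fixed embryo libraries held transcripts of heart, liver and trunk. Myl7, an atrial myosin light chain, stood at 2431 ± 466 TPM (SD, n = 6), Afp, a fetal liver and yolk sac protein, at 287 ± 106 TPM, and Hoxb9, a trunk patterning factor, at 533 ± 95.5 TPM. The libraries labelled E10.5 fresh-frozen embryo had 4.63 ± 4.79 TPM of Myl7, 0.17 ± 0.42 TPM of Afp and 0.184 ± 0.207 TPM of Hoxb9 (n = 6). They instead held late neuronal transcripts, with the AMPA receptor subunit Gria2 at 341 ± 67.9 TPM against 1.0 ± 0.51 TPM in the fixed embryo, 18.4 ± 2.46 TPM in E12.5 brain (n = 4) and 87.2 ± 11.6 TPM in E16.5 brain (n = 4). Embryonic beta-globins made up 99.4 ± 0.11% of beta-globin TPM in the fixed embryo, 97.5 ± 0.24% in E12.5 brain and 1.75 ± 0.35% in E16.5 brain, against 12.7 ± 4.69% in the fresh-frozen libraries. Across 23308 genes, the fresh-frozen libraries had a mean Pearson r of 0.852 with E16.5 brain (range 0.835 to 0.876) and 0.685 with the fixed embryo (range 0.654 to 0.731). The tables were normalized separately and genes are not independent replicates. Where a direction below is drawn from the libraries labelled E10.5 fresh-frozen embryo, it is drawn from libraries with this late-brain content. Xist, the X-inactivation RNA, was at 125 ± 24.0 TPM in the fixed embryo and 267 ± 37.1 TPM in E12.5 brain. The Y-linked Ddx3y was at 42.0 ± 2.95 TPM in the fresh-frozen libraries and 18.1 ± 2.69 TPM in E16.5 brain, so tables also differed in sex.

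**Figure D1:**
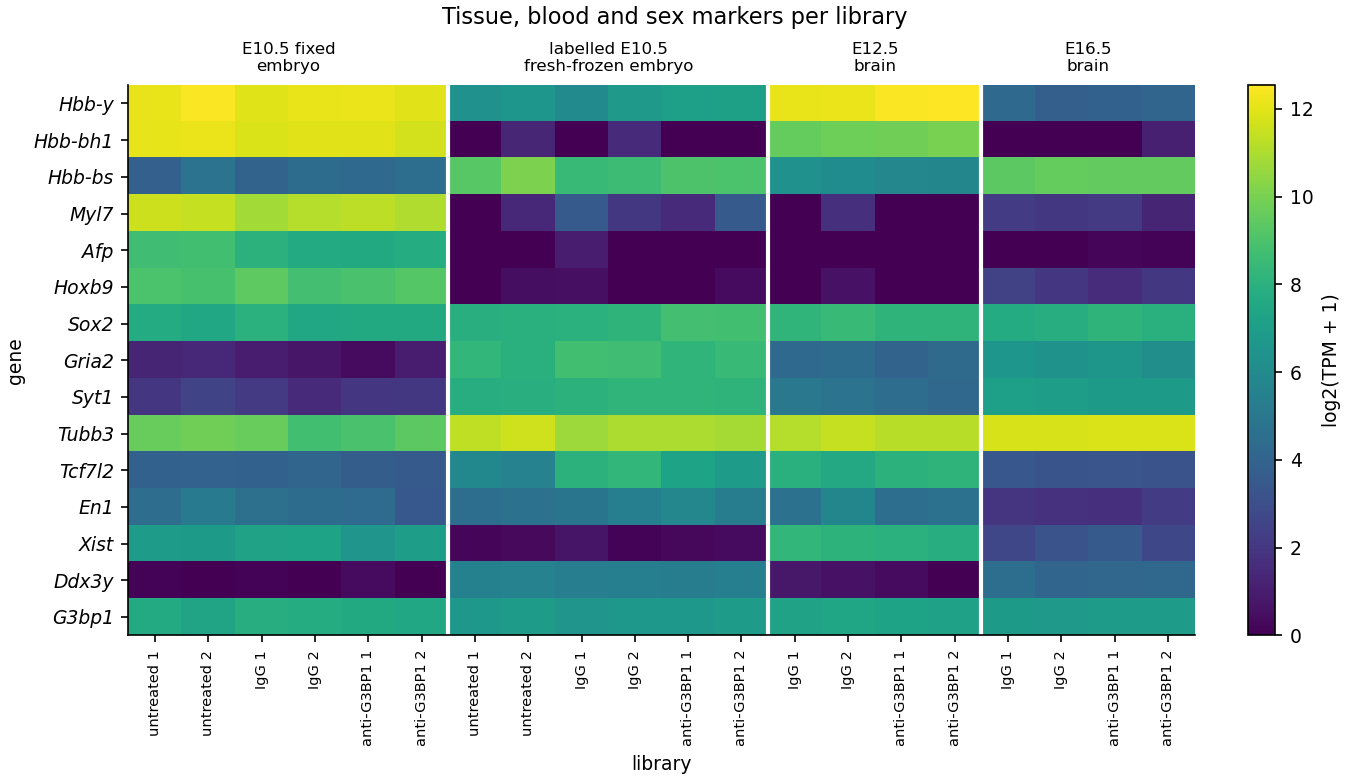
Levels of tissue, globin and sex-linked marker genes (vertical axis) in each of the 20 libraries (horizontal axis), as log2(TPM + 1) in colour. Hbb-y and Myl7 were high in the fixed embryo, whereas Gria2 was highest in the libraries labelled E10.5 fresh-frozen embryo.

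Whether the antibody raised editing above the IgG background was asked first for all kept sites together. The edited share of reads was higher with anti-G3BP1 than with IgG in all 4 tables. It was 1.23 ± 0.019% against 0.648 ± 0.018% (SD, n = 2 each) in the libraries labelled E10.5 fresh-frozen embryo, a 1.90-fold difference. In E12.5 brain it was 0.401 ± 0.039% against 0.206 ± 0.011%, or 1.95-fold, and in E16.5 brain 0.360 ± 0.020% against 0.222 ± 0.008%, or 1.62-fold. The fixed embryo had 0.485 ± 0.009% against 0.382 ± 0.028%, or 1.27-fold. The mean log2 difference over the 4 tables was 0.73 (1.66-fold, exact two-sided permutation p = 0.00154 within tables, the smallest that the 1296 arrangements can give). A-to-G sites gained 1.91-fold (mean log2 0.93) and C-to-T sites 1.45-fold (mean log2 0.53), each with the same permutation p of 0.00154. Untreated fresh-frozen libraries had 0.368 ± 0.017%, below their IgG libraries. Untreated fixed libraries had 0.477 ± 0.124% (0.390% and 0.565%), so in the fixed embryo the anti-G3BP1 level lay within the spread of the untreated background. The fixed IgG mean of 0.382% lay below the untreated mean. The 0.565% came from untreated replicate 2, which had the lowest depth of the fixed libraries (33.8 reads per kept site). As each table holds its own set of sites, in the brain tables many without any edited read, shares are compared within tables only. With 1997345 to 63989003 reads at kept sites per library the counting error of a share is small, for example 0.192 to 0.203% (95% Wilson interval) around 0.198% in E12.5 IgG replicate 1. Such intervals and floors cover counting error only, since reads carried no molecular identifiers.

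**Figure D2:**
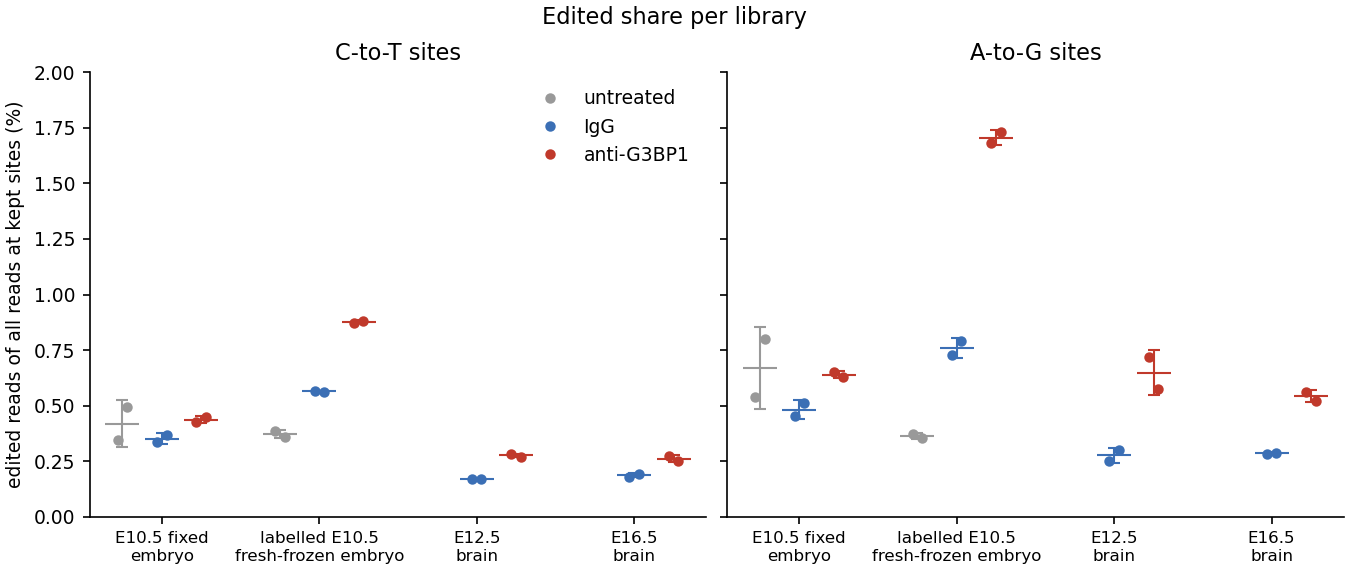
Edited reads as a percentage of all reads at kept C-to-T (left) and A-to-G (right) sites, by table; each point is a library, bars are the mean and SD of 2 libraries. With anti-G3BP1 the share was above that with IgG in each of the 4 tables.

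Averaged over the tables, the gain was largest in 3' untranslated regions, but in the fixed embryo it was smallest there. Edited shares in these regions were 1.19, 2.09, 1.98 and 1.73 times those with IgG in the fixed, fresh-frozen, E12.5 and E16.5 tables (mean log2 0.77), against 1.27, 1.57, 1.89 and 1.44 times in coding sequence (0.61). In the same order, sites in 5' untranslated regions had 1.22, 1.21, 1.83 and 1.17 times (0.41) and those in non-coding exons 1.38, 1.18, 1.73 and 1.22 times (0.45). Each of the 4 regions passed at an exact permutation p of 0.00154. The gain also varied with the base before the site. C-to-T sites after an A gained by a mean log2 of 0.91 and those after a T by 0.48 (permutation p = 0.00154 each), whereas those after a C gained by 0.19 (permutation p = 0.123) and those after a G by 0.20 (permutation p = 0.0170). A-to-G sites after a T gained by 1.18 and those after an A by 1.1, against 0.47 after a G. The differences between regions or between bases were not tested.

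In the libraries labelled E10.5 fresh-frozen embryo, editing rose over IgG on single genes of the neuronal cytoskeleton, of axon guidance and of the synapse. Genes were called against no change, while the median log2 odds change of all genes was 0.91. A call therefore does not mark a gain beyond that of other genes. Tuba1a, a neuronal alpha-tubulin on chromosome 15, went from 0.55 ± 0.06% of reads with IgG to 4.46 ± 0.23% with anti-G3BP1 (SD, n = 2 each), with 0.167 ± 0.038% in untreated libraries. Its log2 odds change was 3.05 ± 0.42 (SE, adjusted p = 1.17e-09), and its kept sites are partly listed under another gene as well. Among dendritic microtubule proteins, Map2 rose from 0.591 ± 0.312% to 1.93 ± 0.27% (log2 1.78, adjusted p = 2.11e-10) and Map1b from 0.803 ± 0.022% to 1.86 ± 0.17% (log2 1.23, adjusted p = 1.42e-07). The microtubule destabilizer Stmn2 rose from 0.737 ± 0.090% to 3.74 ± 0.50% (log2 2.35, adjusted p = 1.46e-05). Dcc, the netrin receptor, rose from 1.2 ± 0.16% to 3.37 ± 0.37% against 0.164 ± 0.068% in untreated libraries (log2 1.52, adjusted p = 2.43e-08).

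Called genes fell in several of the fixed gene lists. Of 25 neuronal cytoskeleton genes tested, 8 rose, 14 passed when adjusted over the list alone, and the list ranked above other genes (cameraPR adjusted p = 6.39e-12). No list of this table was called with an estimated correlation, at an adjusted p = 0.995 with an estimated correlation for those below and 1.0 for the synapse list. Against the median change of all genes, neuronal cytoskeleton genes alone still ranked above others (adjusted p = 0.00185) and nuclear long non-coding RNAs ranked below (4.98e-06). The other lists below were not called by that measure, with axon guidance genes at 0.18, and long neuronal FMRP targets (0.949), long chromatin genes (0.904) and synapse genes (0.508) then pointing down. Axon guidance genes rose in 7 of 28 cases (10 adjusted over the list alone, list adjusted p = 0.000116), among them the Slit receptors Robo2 (log2 1.62, adjusted p = 0.00663) and Robo1 (2.88, 0.00711) and the ephrin Efna5 (1.70, 0.0231). Long neuronal FMRP targets rose in 5 of 30 cases (9 adjusted over the list alone, list adjusted p = 9.26e-06), with the ankyrins Ank2 (log2 1.22, adjusted p = 0.000296) and Ank3 (0.95, 0.00156) and the Wnt regulator Apc (1.31, 0.000372). The synapse list had 4 of 33 genes higher (8 adjusted over the list alone, list adjusted p = 0.0364), among them the vesicle protein Sv2a (log2 1.58, adjusted p = 0.00015, but -0.83 with C-to-T sites alone), the glutamate receptor subunit Grin2b (1.07, 0.015) and the adhesion protein Nlgn3 (1.48, 0.0169). Long chromatin genes had 2 of 22 higher, Bptf (log2 1.52, adjusted p = 0.00237) and Crebbp (2.02, 0.0224), with 5 adjusted over the list alone and a list adjusted p of 0.00175. RNP granule proteins had 1 of 19 higher (2 adjusted over the list alone, list adjusted p = 0.0364), the decapping activator Ddx6 (log2 1.47, adjusted p = 0.015, but -0.54 with C-to-T sites alone). Reference stress-granule mRNAs had 1 of 7 higher (4 adjusted over the list alone, list adjusted p = 0.0312), Zfp704 (2.22, 0.0185). Neural crest and peripheral genes had 2 of 6 higher (4 adjusted over the list alone, list adjusted p = 0.0113), the neurotrophin receptors Ntrk3 (log2 1.30, adjusted p = 0.0375, but -0.15 with C-to-T sites alone) and Ntrk2 (1.98, 0.038). Ribosomal protein genes ranked below other genes (0 of 43 called by the quasi-binomial test, median log2 0.02, list adjusted p = 0.00148).

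The largest called changes outside these lists were in Oga, the enzyme that removes O-GlcNAc (log2 3.81, adjusted p = 0.0441), the lipid phosphatase Plpp3 (3.8, 0.0434), Isg20l2 (3.39, 0.0434) and the Golgi GTPase Arf4 (3.27, 0.0265). Next came the ubiquitin ligase Cbl (3.25, 0.00557), Ndfip1 (3.24, 0.003), the glycine receptor subunit Glra2 (3.20, 0.0179), Eif4b (3.09, 0.0441) and Cox4i1 (3.07, 0.000801, from 1 site). G3bp2 (log2 1.48, adjusted p = 0.076), Caprin1 (1.15, 0.236) and G3bp1 (0.39, 0.741) did not pass. In all, 225 of 7824 genes were higher and 0 lower in the quasi-binomial test. The median log2 odds change of all genes was 0.91, and 1086 genes had an unadjusted p under 0.05, 7 of them lower. Against that median 3 genes were higher, Tuba1a, Rtn4 and Hnrnpa0, and 6 lower (Rtn4 and Hnrnpa0 were chosen after their values were seen). The count was 8 without IgG replicate 1, 17 without IgG replicate 2, 130 without anti-G3BP1 replicate 1 and 103 without replicate 2. With all libraries edgeR gave 132, limma 0 (1212 at an unadjusted p under 0.05), C-to-T sites alone 0 and A-to-G sites alone 137.

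In E16.5 brain, editing rose over IgG on single genes of the cytoskeleton, of RNP granules, of protein folding and of translation. These calls too were against no change, with a median log2 odds change of 0.67 over all genes. Map1b rose from 0.113 ± 0.012% to 0.271 ± 0.023% of reads (SD, n = 2 each, log2 1.22 ± 0.16, adjusted p = 3.66e-10). The neuronal beta-tubulin Tubb3 rose from 0.0959 ± 0.0015% to 0.222 ± 0.023% (log2 1.24, adjusted p = 2.37e-05, but -0.28 with C-to-T sites alone) and the kinesin Kif5c from 0.0983 ± 0.0035% to 0.230 ± 0.028% (log2 1.2, adjusted p = 4.27e-05). Caprin1, a partner of G3BP1 in granules, rose from 0.214 ± 0.060% to 0.507 ± 0.196% (log2 1.27, adjusted p = 2.7e-07), and Fmr1, the fragile X protein gene, from 0.324 ± 0.193% to 1.34 ± 0.11% (log2 2.15, adjusted p = 0.00315). The chaperone Hsp90ab1 rose from 0.0946 ± 0.0152% to 0.262 ± 0.079% (log2 1.37, adjusted p = 9.71e-06). No untreated brain library is among the samples, so IgG is the only background here.

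Of 25 neuronal cytoskeleton genes, 12 rose, 19 passed when adjusted over the list alone, and the list ranked above other genes (cameraPR adjusted p = 3.93e-17). No list of this table was called with an estimated correlation (adjusted p = 0.622 with an estimated correlation for each list below). Against the median change of all genes, only neuronal cytoskeleton genes and RNP granule proteins still ranked above others (adjusted p = 0.0267 each), and nuclear long non-coding RNAs ranked below (0.000192). The other lists below were not called by that measure, with axon guidance genes at 0.629, long neuronal FMRP targets at 0.982 and synapse genes, then pointing down, at 0.842. RNP granule proteins rose in 8 of 20 cases (12 adjusted over the list alone, list adjusted p = 4.28e-06), with the helicase Ddx3x (log2 1.41, adjusted p = 0.000552) and G3bp2 (1.23, 0.0163) among them. Axon guidance genes rose in 8 of 29 cases (13 adjusted over the list alone, list adjusted p = 1.23e-05), including Dcc (log2 1.16, adjusted p = 4.93e-06), Robo2 (1.08, 0.00185) and the adhesion molecule Cntn2 (1.1, 0.0113). Long neuronal FMRP targets rose in 8 of 30 cases (12 adjusted over the list alone, list adjusted p = 0.000226), with Ank3 (log2 0.94, adjusted p = 0.000921), Ank2 (0.95, 0.00189) and the amyloid precursor App (0.77, 0.00246). Among translation factors 5 of 21 rose (8 adjusted over the list alone, list adjusted p = 0.0171), led by Eif3a (log2 1.87, adjusted p = 0.000203), Eif4a2 (1.02, 0.000323) and Eif4g2 (0.86, 0.00139). Heat shock and unfolded protein genes had 2 of 12 higher, Hsp90ab1 and Hsph1 (log2 1.87, adjusted p = 0.000647), with 2 adjusted over the list alone and a list adjusted p of 0.0122. Neural progenitor genes rose in 6 of 22 cases (8 adjusted over the list alone, list adjusted p = 0.0174), among them the glial receptor phosphatase Ptprz1 (log2 0.99, adjusted p = 1.89e-07), the glutamate transporter Slc1a3 (1.65, 0.00139), Notch1 (1.62, 0.00739) and Sox2 (1.19, 0.0299). The synapse list had 5 of 35 higher (6 adjusted over the list alone, list adjusted p = 0.0171), with Sv2a (log2 1.09, adjusted p = 0.000188) and Syn1 (1.84, 0.017). Imprinted growth genes had 6 of 15 higher (9 adjusted over the list alone, list adjusted p = 0.000569), with Grb10 (log2 1.43, adjusted p = 0.00583) and Dlk1 (1.82, 0.0112). For long chromatin genes, 5 of 22 were higher (9 adjusted over the list alone, list adjusted p = 0.000265), with Arid1a and Atrx. Genes with known A-to-I recoding had 2 of 23 higher (8 adjusted over the list alone, list adjusted p = 0.0174), with Cadps. Cortical layer genes had 2 of 18 higher (9 adjusted over the list alone, list adjusted p = 0.0122), with Pou3f3 and Tbr1. Ribosomal protein genes again ranked below other genes (0 of 70 called by the quasi-binomial test, median log2 0.45, list adjusted p = 0.00737).

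The largest changes in E16.5 brain were in the cyclin Ccnh (log2 3.66, adjusted p = 0.0416), Rpia of the pentose phosphate pathway (3.36, 0.0316), Tmem167b (3.22, 0.0421), and Rbbp9 (2.82, 0.00931). They were followed by the vesicle tether Uso1 (2.75, 0.0431), the mitophagy receptor Fundc1 (2.70, 0.0245), Plaa (2.66, 0.000496), catalase Cat (2.66, 0.0315), the kinase Mknk1 (2.59, 0.0261) and Ankrd6 (2.56, 2.7e-07). G3bp1 itself had 0.30 ± 0.004% against 0.133 ± 0.046% (log2 1.11, adjusted p = 0.109) and did not pass. Of 11574 genes 694 were higher and 0 lower in the quasi-binomial test. The median log2 odds change was 0.67, and 2065 genes had an unadjusted p under 0.05, 11 of them lower. Against the median 4 genes were higher, Ankrd6, Cct6a, Myo5a and Tspyl1 (the last 3 chosen after their values were seen), and 18 lower. Without IgG replicate 1 the count was 20, without IgG replicate 2 it was 105, without anti-G3BP1 replicate 1 it was 337 and without replicate 2 it was 358. By limma it was 0 (1445 at an unadjusted p under 0.05), edgeR 709, C-to-T sites alone 30, A-to-G sites alone 400, reads thinned to the shallowest library 265 and a replicate block 453.

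**Figure D3:**
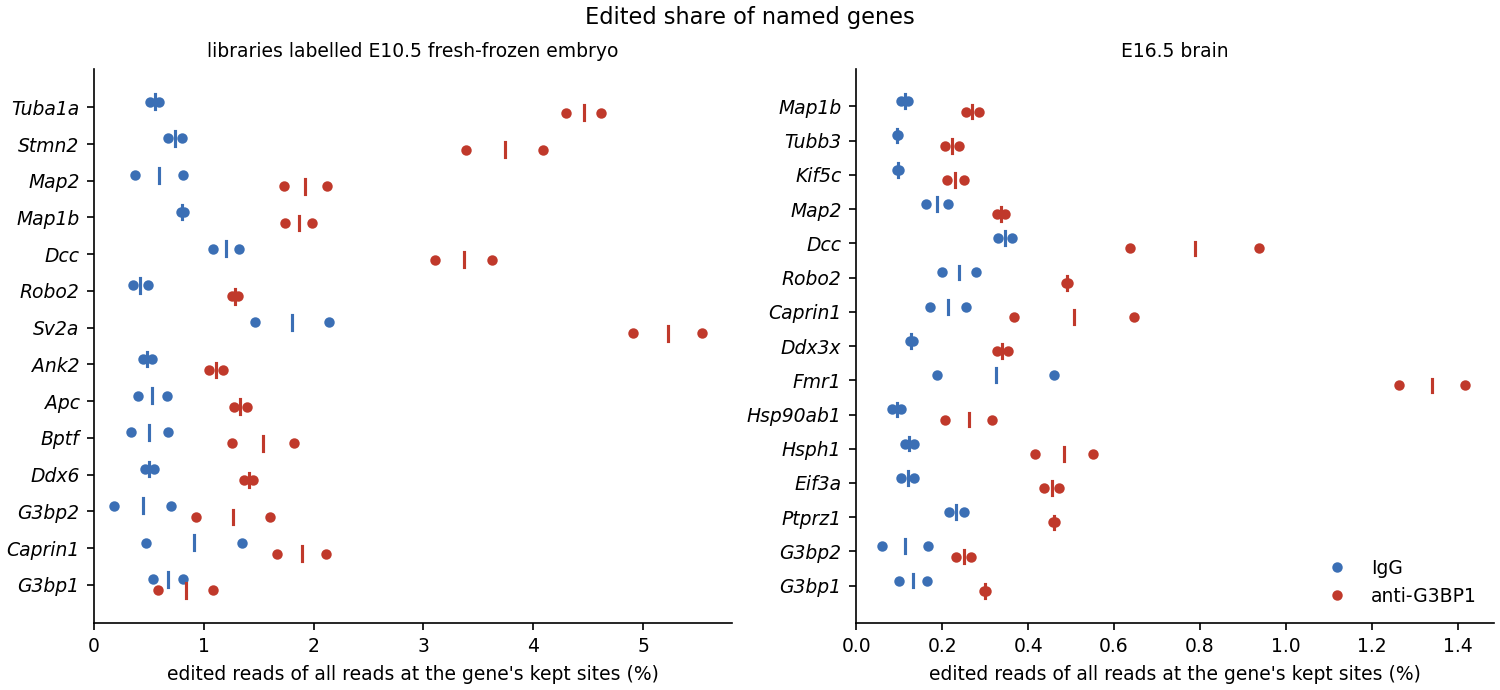
Edited reads as a percentage of all reads at each gene's kept sites (horizontal axis) for named genes, in the libraries labelled E10.5 fresh-frozen embryo (left) and in E16.5 brain (right); points are libraries and bars means of 2. Tuba1a reached 4.46% with anti-G3BP1 in the former, Map1b 0.271% in the latter, and G3bp1 did not pass the test in either.

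Few single genes passed in the other tables. In E12.5 brain, Chd7, a chromatin remodeller of neural crest and hindbrain, went from 0.325 ± 0.365% to 2.01 ± 1.79% (SD, n = 2 each, log2 2.15 ± 0.48, adjusted p = 0.0317). In the fixed embryo, Rps19-ps6, a processed pseudogene on chromosome 12 (110898114 to 110898551, GRCm38), went from 18.2 ± 2.22% to 28.2 ± 8.66% with 22.2 ± 0.75% in untreated libraries (log2 0.83 ± 0.10, adjusted p = 2.94e-13). Its reads may come from near-identical copies. Hsp90ab1 in E12.5 brain stood at 0.424 ± 0.298% against 0.0833 ± 0.0416% (log2 2.04, adjusted p = 0.423) and did not pass, nor did Tcf7l2 (1.31, 0.849), mt-Nd5 (1.52, 0.542), Map1b (1.16, 0.849) or Map2 (1.16, 0.849). Caprin1 (log2 2.19), G3bp2 (1.58) and G3bp1 (1.09) each had an adjusted p of 0.849 there. In the fixed embryo G3bp2 (1.88), G3bp1 (0.61) and Caprin1 (0.38) each had 0.978. As lists, heat shock and unfolded protein genes ranked above other genes in E12.5 brain (0 of 8 called, median log2 1.36, 1 adjusted over the list alone, cameraPR adjusted p = 0.00437). So did forebrain transcription factors (0 of 6, 1 adjusted over the list alone, 0.00437) and mitochondrially encoded genes (0 of 7, 2 adjusted over the list alone, 0.00955). Neuronal cytoskeleton genes (0 of 25, 0 adjusted over the list alone, median 1.15, 0.0108), long chromatin genes (1 of 20, Chd7, also adjusted over the list alone, 0.0134) and secretory pathway genes (0 of 20, 0 adjusted over the list alone, 0.0332) did too. None was called with an estimated correlation (adjusted p = 0.799 with an estimated correlation) or against the median change (smallest adjusted p = 0.277). In the fixed embryo no list was called (smallest adjusted p = 0.0519, for cell cycle and for heat shock genes).

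The quasi-binomial test called 1 of 5575 genes in the fixed embryo and 1 of 4972 in E12.5 brain, each higher, with 128 and 133 genes at an unadjusted p under 0.05 and a median log2 odds change of 0.30 and 0.84. Calls by edgeR were 0 in both (189 and 226 unadjusted), and limma called 0 and 1, the latter lower (330 and 302 unadjusted). Rps19-ps6 lost its call without anti-G3BP1 replicate 1 (0 genes) and turned to -1.20 with C-to-T sites alone and to -1.64 without sites edited in 50% of reads or more. In E12.5 brain the count was 0 without either IgG library, 3 without anti-G3BP1 replicate 1 and 24 without replicate 2, and Chd7 was not called with C-to-T sites alone or A-to-G sites alone. Against the median change, Rps19-ps6 was higher and Gm4332 lower in the fixed embryo, and Rps19-ps6 and Gm6789 were lower in E12.5 brain (the pseudogenes Gm4332 and Gm6789 were chosen after their values were seen). On simulated data with a log2 change of 2, the test recovered 58% of changed genes in the fixed embryo and 59% in the fresh-frozen libraries. It recovered 45% in E12.5 brain and 80% in E16.5 brain. The changes were placed on genes with more edited reads, so recovery over all tested genes may be lower. The simulated libraries also held no general gain, and their replicates varied only by the drawing of reads in pairs. Recovery in the data may differ for that too. With a log2 change of 1, closer to the observed medians, the quasi-binomial test recovered 1, 8, 5 and 19%. At a log2 change of 2, edgeR recovered 13, 17, 14 and 52% and limma 0, 0, 1 and 0%. A limma count of 0 in any of these tables therefore says little.

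How G3BP1 contacts differ between labelled stages and preparations was asked in 2 ways. Shared calls were common between the libraries labelled E10.5 fresh-frozen embryo and E16.5 brain: of 6972 genes tested in both, 199 and 629 were called and 112 in both, among them Map1b, Map2, Dcc, Ank2 and Ank3. That is above the 60.1 expected among genes of like read number (exact stratified p = 5.93e-18) and the 18.0 expected without regard to reads. Calls were made against no change, and most genes rose in both tables. Shared calls may thus mark genes with enough edited reads to show a general gain. The exact p also treats genes as independent. The genes higher against the median change were different ones in the 2 tables. Across the 6972 genes the log2 odds changes correlated weakly (Pearson r 0.105, Spearman rho 0.146, across genes that are not independent replicates). Tests of the difference itself called 0 genes: 0 of 2796 for E16.5 against E12.5 brain, 0 of 1183 for E12.5 brain against the fresh-frozen libraries and 0 of 426 for fresh-frozen against fixed, by the quasi-binomial model, with 65, 29 and 4 genes at an unadjusted p under 0.05. By edgeR, 0 were called as well (114, 45 and 9 unadjusted), and limma had 197, 123 and 18 unadjusted. The median standard error of a difference was 2.04, 2.87 and 3.15 on the log2 scale. Simulated differences of log2 2, placed on genes with more edited reads, were recovered in 5, 1 and 8.16% of cases. Single-gene differences of that size were thus seldom detected. For G3bp1, the E16.5 minus E12.5 difference was -2.14 ± 2.76 (SE, adjusted p = 0.997). Stage changes together with table, and the first comparison of brains also with tissue content (below). Comparisons with the libraries labelled E10.5 fresh-frozen embryo also change tissue content, given their late-brain transcripts (above). They therefore isolate neither the labelled stage nor the preparation.

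All sites of a list were also pooled. Relative to all other sites, transcripts of heat shock and unfolded protein genes gained more editing in each of the 4 tables (log2 0.63, 0.22, 0.61 and 0.37 in the fixed, fresh-frozen, E12.5 and E16.5 tables, mean 0.46, exact permutation p = 0.00154, adjusted p = 0.0239). Without the gene with the most reads in each table (Hsp90ab1, with 37.5% of the list's reads, in E12.5 brain) the mean was 0.35 (permutation p = 0.00463) and the E12.5 gain fell from 0.61 to 0.30. Their IgG share was below that of other sites in each table, for example 0.117% against 0.206% in E12.5 brain. In percentage points the gain exceeded that of other sites by 0.0454 (permutation p = 0.0725) and did not pass. Nuclear long non-coding RNAs gained less in each (-0.57, -0.83, -0.28 and -0.49, mean -0.54, exact permutation p = 0.00154, adjusted p = 0.0239). Their E16.5 share was 0.163 ± 0.012% with anti-G3BP1 against 0.141 ± 0.004% with IgG. Matched to sites of the same edit type, preceding base and region, their mean was -0.27 (permutation p = 0.0725) and did not pass. Ribosomal protein transcripts, whose mRNAs are short, also gained less in each (mean -0.31, permutation p = 0.00309, adjusted p = 0.0319). Against sites of the same edit type, preceding base and region the mean was -0.20 (permutation p = 0.0123), with E16.5 moving from -0.22 to -0.09. Nuclear genes of the respiratory chain (mean 0.27, adjusted p = 0.109), axon guidance genes (0.22, 0.227), neuronal cytoskeleton genes (0.17, 0.33) and synapse genes (-0.08, 0.851) did not pass by this permutation measure, which was chosen after the data were seen. Nor did RNP granule proteins (0.04, 0.851) and reference stress-granule mRNAs (0.07, 0.851). By table the former were at -0.04, 0.07, -0.15 and 0.29 and the latter at -0.03, -0.05, 0.40 and -0.04. Synapse sites gained less than other sites in 3 of 4 tables, by -0.29 in the fresh-frozen table.

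**Figure D4:**
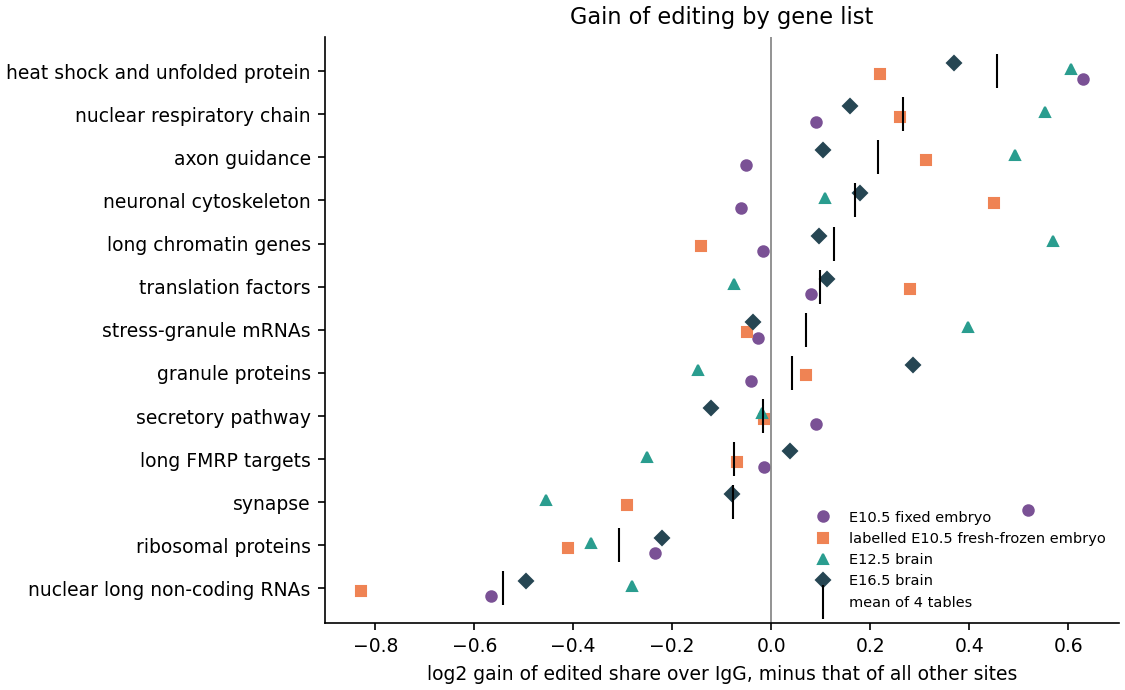
Log2 gain of the edited share with anti-G3BP1 over IgG for the sites of each gene list, minus that of all other sites (horizontal axis); symbols are the 4 tables and bars their mean. Heat shock and unfolded protein genes lay above 0 and nuclear long non-coding and ribosomal protein transcripts below 0 in each of the 4 tables.

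How far the treated transcriptomes differ from untreated ones was asked for each E10.5 table. In the labels, antibody libraries carry a formaldehyde fixation and untreated libraries carry none. By that label, treatment and fixation change together in this contrast and cannot be told apart. In the fixed embryo, however, titles call the untreated libraries fixed as well. Whether fixation changes with treatment there is thus open. In the libraries labelled E10.5 fresh-frozen embryo, several cortical and proliferation genes were lower in treated sections than in untreated ones. The treated group pools IgG and anti-G3BP1 libraries, which themselves differed in such genes, for example in Mki67 (24.1 and 52.5 TPM). Among the largest single increases were hypothalamic and midbrain genes, picked by their change and not tested as a set. The neuropeptide Avp was at 126 ± 21.3 TPM (SD, n = 4) against 9.29 ± 0.86 TPM (n = 2, log2 3.61, limma adjusted p = 0.000238), and the midbrain factor En2 at 134 ± 21.9 against 26.9 ± 1.70 TPM (log2 2.26, adjusted p = 0.00162). Six6 (log2 3.03, adjusted p = 0.00376), Rax (2.11, 0.0104) and Six3 (1.36, 0.00268), eye and hypothalamus factors, rose, as did Cartpt (2.89, 0.00669), Foxb1 (2.06, 0.00473), Cck (2.02, 0.0317) and the proteasome subunit Psma8 (3.91, 0.00202). Neurod6, a cortical neuron factor, was at 68.2 ± 29.6 TPM against 504 ± 8.65 TPM and fell by 2.98 on the log2 scale (adjusted p = 0.0052). Eomes (-3.20, 0.00848) and Tbr1 (-1.91, 0.00271), further cortical factors, fell as well, along with Rspo1 (-2.58, 0.0291) and Cdca7 (-2.54, 0.0115). The list of midbrain and hindbrain genes was not called (4 higher and 3 lower of 20, 15 adjusted over the list alone, median log2 0.44 but mean -0.20, list adjusted p = 0.203). Cell cycle genes fell in 14 of 28 cases (23 adjusted over the list alone, list adjusted p = 6.34e-13, 0.54 with an estimated correlation), among them Ccnb1 (log2 -2.16), Mcm4 (-1.34) and Ccna2 (-1.23). Translation factors had 1 higher and 12 lower of 21 (14 adjusted over the list alone), ranking below other genes (list adjusted p = 1.05e-09, 0.405 with an estimated correlation), with Eef1a1 (log2 -1.1), Eif4g2 (-0.94) and Eef2 (-0.84) lower and Eif4a1 (1.07) higher. Nuclear long non-coding RNAs rose in 5 of 11 cases (6 adjusted over the list alone, list adjusted p = 3.47e-05, 0.454 with an estimated correlation), with Malat1 (log2 1.26), Snhg11 (1.16) and Meg3 (1.04).

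RNP granule genes had 2 higher and 5 lower of 20 in the same contrast and ranked below other genes (8 adjusted over the list alone, list adjusted p = 0.00755, 0.54 with an estimated correlation). Caprin1 fell by 1.14 on the log2 scale (adjusted p = 0.00239), Pabpc1 fell by 0.97, Ddx3x fell by 0.84 and G3bp2 fell by 0.66 (adjusted p = 0.007), whereas G3bp1 did not pass (-0.09, adjusted p = 0.717). Interneuron genes ranked below other genes (2 higher and 8 lower of 20, 14 adjusted over the list alone, list adjusted p = 0.00157, 0.405 with an estimated correlation), with Calb2 (log2 -1.57) and Lhx6 (-1.33) lower and Sst (1.39) higher. Cortical layer genes also did (1 higher and 5 lower of 18, 7 adjusted over the list alone, list adjusted p = 0.0251, 0.54 with an estimated correlation), although Nrn1 (1.29) rose. Heart genes ranked above other genes (3 of 6 higher, 4 adjusted over the list alone, list adjusted p = 0.00755, 0.405 with an estimated correlation), with Nppa (log2 1.84) and Tnni3 (1.49). Eye genes did as well (3 of 10 higher, 3 adjusted over the list alone, list adjusted p = 0.00755, 0.54 with an estimated correlation). A regional marker moved with the groups: Tcf7l2 of the thalamus was at 265 and 314 TPM with IgG, 153 and 120.5 TPM with anti-G3BP1 and 57.2 and 46.0 TPM without treatment. In limma 1311 of 23545 genes were higher and 1254 lower. The total was 460 without untreated replicate 2, 691 without untreated replicate 1, 1220.0 without IgG replicate 2, 1406 without anti-G3BP1 replicate 2 and 1694 with a replicate block.

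In the fixed embryo 0 of 19144 genes passed in limma (2243 at an unadjusted p under 0.05). Untreated replicate 2 stood apart, with 17310 genes at 1 TPM or more against 17761 to 18054 in the other fixed libraries. Its mitochondrial share of TPM was 11.3% against 8.58 to 10.04%, and its haemoglobin share 1.95% against 1.36 to 1.57%. Its mean depth of 33.8 reads per kept site was the lowest of the fixed libraries. Liver and gut genes ranked below other genes in treated sections (7 of 18 adjusted over the list alone, list adjusted p = 1.47e-08, 0.991 with an estimated correlation). Apoa1 was at 87.3 ± 15 against 210.5 ± 17 TPM (log2 -1.27, adjusted p = 0.123), Ttr at 93.6 ± 13.4 against 200.3 ± 18.3 TPM (-1.1, 0.123) and Afp at 219.9 ± 32.8 against 420.0 ± 2.13 TPM (-0.94, 0.137). Neuronal cytoskeleton genes ranked below as well (2 of 25 adjusted over the list alone, list adjusted p = 4.73e-09, 0.991 with an estimated correlation), with Nefl at 110.1 ± 36.6 against 227 ± 24.4 TPM (log2 -1.1, adjusted p = 0.242).

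Between anti-G3BP1 and IgG, few transcript levels passed the test in any table. On simulated data with a log2 change of 2 it recovered 69% of changed genes in the fixed embryo, 52% in the fresh-frozen libraries, 0% in E12.5 brain and 90% in E16.5 brain, and with a log2 change of 1 it recovered 37, 10, 0 and 62%. Low counts therefore do not show unchanged levels, least of all in E12.5 brain. In E16.5 brain Sfrp2, a secreted Wnt modulator of cortical progenitors, rose from 49.0 ± 0.06 to 176 ± 21.1 TPM (SD, n = 2 each, log2 1.82, limma adjusted p = 0.00782), and Gm26771 rose (log2 1.59, adjusted p = 0.0302; an unnamed transcript mentioned after its value was seen). The progenitor genes Ednrb (log2 0.85, adjusted p = 0.0689) and Fabp7 (0.40, 0.284) did not pass. Neural progenitor genes nevertheless ranked above others there (list adjusted p = 8.04e-16, 9 adjusted over the list alone, 0.492 with an estimated correlation). Nuclear long non-coding RNAs ranked below (list adjusted p = 1.19e-07, 6 adjusted over the list alone, 0.624 with an estimated correlation). In the libraries labelled E10.5 fresh-frozen embryo, intermediate progenitor genes (list adjusted p = 1.43e-34, 14 of 16 adjusted over the list alone), cell cycle genes (1.6e-22, 19 of 28) and neural progenitor genes (9.84e-17, 15 of 23) ranked above others with anti-G3BP1. With an estimated correlation the adjusted p was 0.243, 0.243 and 0.33. IgG replicate 1 stood apart here, with 25508 genes at 1 TPM or more against 20770.0 to 21514 in the other fresh-frozen libraries and Gm10800 as its highest gene at 20669 TPM (picked after its value was seen). Vim was at 391 ± 1.15 against 163 ± 2.30 TPM, Slc1a3 at 55.1 ± 7.39 against 16.7 ± 1.23 TPM and Mki67 at 52.5 ± 1.97 against 24.1 ± 1.28 TPM, each at an adjusted p of 0.147. In the fixed embryo ribosomal protein genes ranked above others (list adjusted p = 3.74e-12, 2 of 77 adjusted over the list alone, 0.965 with an estimated correlation), with Rpl35 at 522 ± 48.2 against 342 ± 15.9 TPM (adjusted p = 0.138). So did mitochondrially encoded genes (list adjusted p = 9.59e-07, 2 of 13 adjusted over the list alone, 0.965 with an estimated correlation), with mt-Co2 at 105 ± 23.2 against 61.5 ± 4.42 TPM (adjusted p = 0.302). In E12.5 brain axon guidance genes (list adjusted p = 4.02e-05, 5 of 29 adjusted over the list alone, 0.766 with an estimated correlation) and ribosomal protein genes (8.45e-05, 10 of 77 adjusted over the list alone, 0.766 with an estimated correlation) ranked below others. The mitochondrial share of TPM was 7.39 and 7.52% with IgG against 5.43 and 5.99% with anti-G3BP1, and the haemoglobin share 0.894 and 0.942% against 1.11 and 1.25%. Of single genes, Barhl1 (27.2 ± 0.41 against 76.0 ± 3.56 TPM), Foxa2 (21.8 ± 1.74 against 59.0 ± 5.84 TPM) and Npy (0 against 54.8 ± 48.6 TPM) had adjusted p of 0.133, 0.134 and 0.133. G3bp1 stayed uncalled in each table, at log2 changes of -0.20, 0.16, -0.07 and 0.11 (fixed, fresh-frozen, E12.5 and E16.5).

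The limma counts were 0 of 18292 genes in the fixed embryo, 0 of 22298 in the fresh-frozen libraries, 0 of 18010 in E12.5 brain and 2 of 18564 in E16.5 brain, with 2085, 2745, 2452 and 1841 genes at an unadjusted p under 0.05. No other tool was run on TPM. Leaving out IgG replicate 2 gave 118, 94, 174 and 9 genes in the 4 tables. Leaving out IgG replicate 1 gave 81 in the fixed embryo and 6 in E12.5 brain, and leaving out anti-G3BP1 replicate 2 gave 1 in the fixed embryo and 68 in E16.5 brain.

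From E12.5 to E16.5, brain libraries gained transcripts of differentiated neurons and lost those of cycling progenitors. All 35 synapse genes tested rose (median log2 1.90), such as Camk2b from 9.42 ± 4.20 to 152 ± 14.1 TPM (SD, n = 4 each, log2 3.95, limma adjusted p = 1.1e-06), Sv2a (2.18, 5.46e-07) and Syt4 (2.14, 1.02e-06). Of 28 cell cycle genes 27 fell (median log2 -1.46), such as Ccnb2 from 210.0 ± 17.6 to 53.1 ± 4.13 TPM (log2 -1.96, adjusted p = 1.54e-06) and Mki67 (-1.73, 2.58e-06). Interneuron genes rose in 20 of 20 cases (median log2 2.35), with Npy (log2 6.32, adjusted p = 0.000756), Dlx1 (2.95, 2.97e-06), Sst (2.39, 3.98e-06) and Lhx8 (4.17, 4.43e-06). Embryonic globins were replaced by adult ones, with Hbb-y at 5136 ± 767 TPM at E12.5 and 15.2 ± 2.45 TPM at E16.5 (log2 -8.31, adjusted p = 1.43e-08), Hbb-bh1 (-9.52, 9.33e-08) and Hba-x (-8.55, 8.73e-08) lower, and Hbb-bs higher (3.50, 3.66e-07).

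By list, the cameraPR adjusted p was 1.78e-32 for synapse genes (35 adjusted over the list alone, 0.241 with an estimated correlation), 2.33e-24 for cell cycle genes (27, 0.241) and 2.05e-10 for interneuron genes (20, 0.264). It was 4.22e-15 for erythroid genes (2 higher and 7 lower of 13, 10 adjusted over the list alone, 0.264). In this paragraph brackets close with the number adjusted over the list alone, the list adjusted p and the adjusted p with an estimated correlation. Neuronal cytoskeleton genes rose in 23 of 25 cases (median log2 1.03, 24, 1.21e-15, 0.324), with Mapt (log2 2.46), Gap43 (1.64) and Stmn2 (1.45). Cortical layer genes had 14 higher and 2 lower of 18 (median log2 1.60, 16, 2.53e-06, 0.376), with Bcl11b (3.59) and Fezf2 (2.34). Astrocyte genes had 12 higher and 1 lower of 15 (median log2 1.80, 13, 0.000625, 0.391), with Tnc (4.78), Aldoc (3.09) and Sparcl1 (3.06). Axon guidance genes had 18 higher and 4 lower of 29 (23, 0.000726, 0.499) and FMRP targets 18 higher and 3 lower of 30 (23, 0.0033, 0.391). A-to-I recoding genes had 17 higher of 23 (18, 3.38e-07, 0.241), among them Gria2 (2.19). Endothelial and pericyte genes had 10 higher of 16 (11, 0.0111, 0.376), with Rgs5 (2.67) and Cldn5 (2.31). Neural progenitor genes had 4 higher and 15 lower of 23 (20, 1.09e-08, 0.376), with Hes5 (-2.84), Nes (-2.50) and Vim (-2.13). Intermediate progenitor genes had 5 higher and 9 lower of 16 (15, 2.91e-07, 0.376), with Neurog1 (-4.33) and Dll3 (-3.01). Ribosomal protein genes had 2 higher and 43 lower of 77 (median log2 -0.33, 46, 1.06e-07, 0.355), with Rps2 (-1.13) lower and Rpl15 (1.26) higher. Mitochondrially encoded genes had 9 lower of 13 (9, 0.00206, 0.264), with mt-Nd6 (-1.39). G3bp1 fell by 0.38 on the log2 scale (152 ± 8.87 to 117 ± 5.65 TPM, adjusted p = 0.00375), G3bp2 rose by 0.70 (adjusted p = 0.000185) and Caprin1 did not pass (0.12, 0.378).

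Regional identity and sex differed between the 2 stages too. The cortical neuron factors Neurod6 (log2 7.18) and Neurod2 (5.07) rose. Midbrain and hindbrain genes had 3 higher and 16 lower of 23 (median log2 -2.66, 20 adjusted over the list alone, list adjusted p = 7.3e-13, 0.264 with an estimated correlation), with En2 (-5.22), Foxa2 (-4.92), Cnpy1 (-4.86), Tal2 (-5.68) and Fzd10 (-4.90) lower. Forebrain transcription factors had 3 higher and 10 lower of 15 (14 adjusted over the list alone, list adjusted p = 4.14e-10, 0.264 with an estimated correlation), with Tcf7l2 (-4.64), Otx2 (-3.99) and Barhl2 (-3.53). Hox genes rose in 17 of 19 cases (median log2 3.61, 17 adjusted over the list alone, list adjusted p = 6.97e-17, 0.241 with an estimated correlation), with Hoxb8 (6.29), Hoxa5 (6.21), Hoxb5 (6.01) and Hoxc4 (5.40). The neuropeptide Avp (5.54) rose and Igdcc3 (-4.99) fell. Xist fell by 5.02 and the Y-linked Eif2s3y (5.46), Ddx3y (3.8) and Kdm5d (3.60) rose. In limma 6516 of 20162 genes were higher and 3573 lower at E16.5, or 5190.0 and 4830.0 after quantile normalization, which moved the median change of all genes from 0.17 to -0.03. The replicate block gave 6602 calls. Stage, dissected region, sex and table change together between these libraries.

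**Figure D5:**
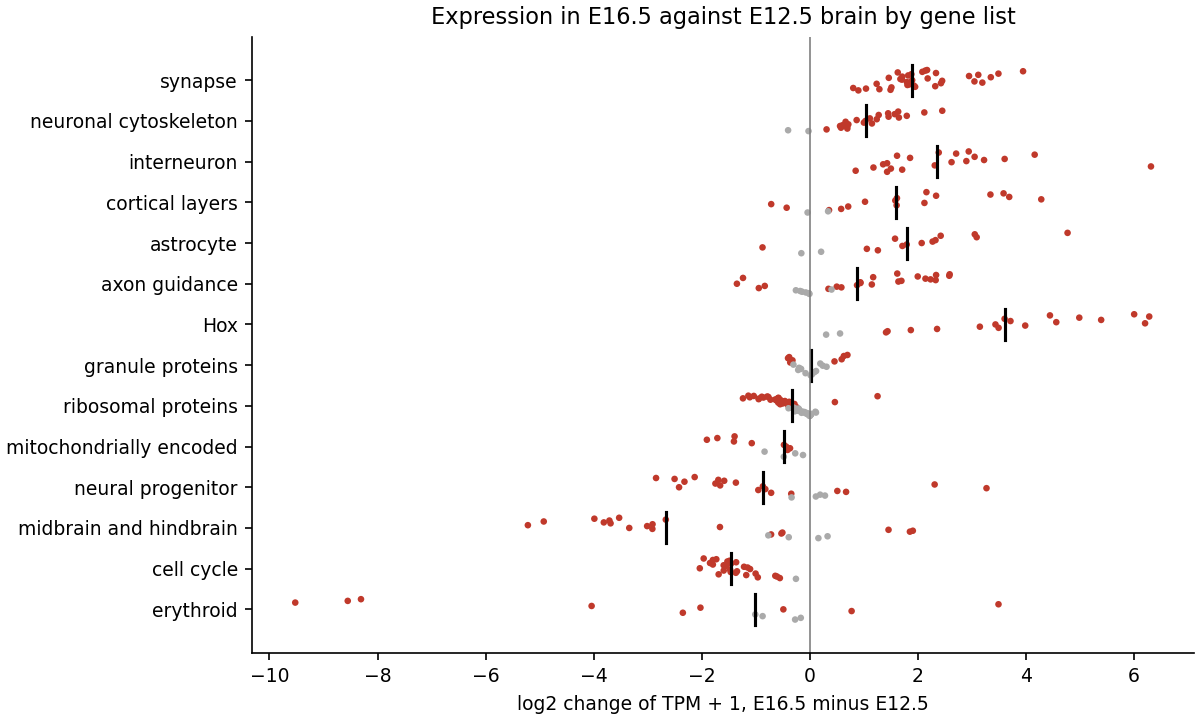
Log2 change in TPM + 1 from E12.5 to E16.5 brain (horizontal axis) for each gene of the lists named on the left; red points passed in limma, grey points did not, and bars are medians. Synapse genes were centred on 1.90 and cell cycle genes on -1.46.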

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

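The tests of the late-brain transcripts, of a strain variant and of editing by the tethered enzyme were chosen only after the result was seen; those of a human sequence and of the nuclear RNAs were fixed before.

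The libraries labelled E10.5 fresh-frozen embryo carried transcripts of late embryonic brain, while the fixed libraries with the same stage in their label carried those of a whole embryo. A section through an E10.5 head would hold embryonic blood, but embryonic forms made up at most 17.4% of beta-globin TPM in a fresh-frozen library against at least 99.3% in the fixed ones. A preparation effect would leave the balance of alpha-globins, yet the Hba-x share was at most 18.7% against at least 81.0%. Libraries of a later stage or another tissue under this label remain a candidate explanation, since the lowest correlation with an E16.5 brain library exceeded the highest with a fixed library by 0.104. A later stage and another tissue were not separated, and whether the label or the section differs is open.

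A signal outside the kept sites stood above the control libraries: at sites in Adarb1, the mouse gene of ADAR2, the edited base made up 76.5% of 187 pooled reads in treated fresh-frozen libraries. A strain variant would also be read in untreated libraries, where 0 of 20 reads had it, which allows up to 15%. Editing of Adarb1 mRNA by the tethered enzyme would not tell silent from other positions, but 6 of 6 sites chosen for a share of 50% or more in a table were silent, where 2.42 were expected of the same base and preceding base (exact one-sided p = 0.00246). Nucleic acid encoding the human enzyme in the treated samples is a candidate source, since these sites, at codons 363, 548, 550, 566, 642 and 649, were silent more often than the 2.27 expected of all possible changes (exact one-sided p = 0.00185). Over sites and tables their share ran from 18.2 to 99.4%, and at codon 649, 1 of 7 untreated reads, from a fixed library, carried the base as well; a biological explanation was not tested.

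Nuclear long non-coding RNAs gained less editing than other sites in 4 of 4 tables. Averaged over the tables, the smaller gain did not rest on the most abundant RNA of each. The mean relative log2 gain without that RNA was -0.54 (exact permutation p = 0.00772). Without Meg3 it moved from -0.28 to -0.11 in E12.5 brain and from -0.49 to -0.62 in E16.5 brain. Nor did a higher background make the fold small. Their IgG share was below that of other sites in the fixed (0.349 against 0.382%), E12.5 (0.166 against 0.206%) and E16.5 tables (0.141 against 0.222%). It was higher in the fresh-frozen table (0.698 against 0.648%), where the gain in percentage points still differed by -0.536. Over the tables this difference was -0.226 (permutation p = 0.00154), although a lower IgG share by itself makes a gain in points smaller. Against sites of the same edit type, preceding base and region the mean relative log2 gain was -0.27 (permutation p = 0.0725). By table it was -0.66, -0.24, -0.11 and -0.07 (fixed, fresh-frozen, E12.5 and E16.5). Without matching it was -0.57, -0.83, -0.28 and -0.49. The matching takes edit type, preceding base and region together, so it cannot tell sequence context from the region of the transcript. Sites in non-coding exons gained 1.18, 1.73 and 1.22 times in the fresh-frozen, E12.5 and E16.5 tables. All sites together gained 1.90, 1.95 and 1.62 times there. How far sequence context alone accounts for the smaller gain stays open. A biological difference, such as a lower contact of cytoplasmic G3BP1 with nuclear RNA, was not tested.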

How the results depend on the processing

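Tests with thinned reads, 1 allele, 1 gene per site, 1 dispersion value, all sites per table, tables left out, top sites left out and the first IgG brain libraries left out were chosen only after the data were seen.

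The overall gain of editing kept its direction under all alternatives and passed under those with 2 libraries per group. With the same replicate of an antibody left out of every table at once, its mean log2 was 0.68 to 0.78 for all sites. It was then 0.51 to 0.56 for C-to-T and 0.86 to 1.01 for A-to-G sites. With thinned reads the mean log2 for all sites was 0.77. The effect of any single library on this gain was not measured. Counts of edited genes moved with depth and replicates; where a library is left out the lone sample is assumed to vary like the other groups. Of the called genes named, 333 of 1020.0 values under other settings and 178 of 292 with a library left out no longer passed, and 7 of 1020.0 reversed; for expression these were 3 of 440.0 and 33 of 694. The planned pseudo-fraction of 0.01 was not run, as reads are given. Where no cause is named, the cause was not tested.

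With C-to-T sites alone the quasi-binomial test called 0 genes in the fixed, 0 in the fresh-frozen, 0 in the E12.5 and 30.0 in the E16.5 table, and 1 gene for E12.5 brain against fresh-frozen. Rps19-ps6 turned to -1.20, Ddx6 to -0.54, Sv2a to -0.83, Ntrk3 to -0.15, Tcf7l2 to -1.39 and Tubb3 to -0.28. With A-to-G sites alone the counts were 137 fresh-frozen, 0 at E12.5 and 400.0 at E16.5, and Caprin1 was at -0.16 in the fixed embryo. Without sites edited in 50% of reads or more, 0 genes were left in the fixed and 0 in the E12.5 table, with Rps19-ps6 at -1.64. Against the median change, counts were 2 fixed, 9 fresh-frozen, 2 at E12.5 and 22 at E16.5, and fresh-frozen G3bp1 was at -0.52. On the empirical logit limma gave 0, 0, 1 (lower) and 0; edgeR gave 0 fixed, 132 fresh-frozen and 0 at E12.5. Thinned reads left 0, 91, 0 and 265 genes, with Rps19-ps6 at 0.00 and G3bp2 at -2.32 in the fixed embryo. Moderation to 1 value gave 373 fresh-frozen and 9 at E12.5. At E12.5, no site minimum, a minimum of 200 reads per gene, 1 allele and 1 gene per site each gave 0.

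With the replicate block, which the labels do not state as pairs and which rests on 2 pairs, the counts were 0 at E12.5 and 453 at E16.5 for editing, 1694 for treatment in the fresh-frozen libraries, 1 for the antibody at E12.5 and 6602 for the brain stages. A pseudocount of 0.1 gave 3 genes for treatment in the fixed embryo, and no filter and quantile normalization each gave 1 gene for the antibody at E16.5.

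With a library left out, edited genes numbered 0 to 1 in the fixed embryo (0 without anti-G3BP1 replicate 1), 8 to 130.0 fresh-frozen (8 without IgG replicate 1, 17 without IgG replicate 2, 103 without anti-G3BP1 replicate 2, 130.0 without replicate 1), and 0 to 24 at E12.5 (0 without either IgG library, 3 without anti-G3BP1 replicate 1, 24 without replicate 2). At E16.5 they numbered 20 to 358 at E16.5 (20 without IgG replicate 1, 105 without IgG replicate 2, 337 without anti-G3BP1 replicate 1, 358 without replicate 2). Differences gave 0 to 1 for E16.5 against E12.5 (1 without E12.5 anti-G3BP1 replicate 2) and 0 to 0 for the others. For the antibody and expression the ranges were 0 to 118 fixed (118 without IgG replicate 2, 81 without IgG replicate 1, 1 without anti-G3BP1 replicate 2), and 0 to 94 fresh-frozen (94 without IgG replicate 2). They were 0 to 174 at E12.5 (174 without IgG replicate 2, 6 without IgG replicate 1) and 2 to 68 at E16.5 (68 without anti-G3BP1 replicate 2, 9 without IgG replicate 2). For treatment they were 0 to 414 fixed (414 without untreated replicate 1) and 460.0 to 2402 fresh-frozen (460.0 and 691 without untreated replicates 2 and 1, 1220.0 without IgG replicate 2, 1406 without anti-G3BP1 replicate 2). For the brain stages they were 8385 to 10358. G3bp1 in fresh-frozen editing ranged from -0.22 without anti-G3BP1 replicate 2 to 0.72 without IgG replicate 2. Its change in level with treatment there ranged from -0.18 without untreated replicate 1 to 0.00362 without untreated replicate 2, and for the antibody at E12.5 from -0.14 without IgG replicate 1 to 0.00711 without IgG replicate 2.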

Other observations

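The count of genes in other splits of the brain libraries was chosen only after the result was seen.

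Known recoding sites were read in some tables without any dependence on the antibody being asked. In the libraries labelled E10.5 fresh-frozen embryo, the Gria2 site at position 80706912 on chromosome 3, in the coding sequence, was edited in 87.1 ± 3.56% of reads with IgG, 78.6 ± 6.01% with anti-G3BP1 and 81.5 ± 2.65% without treatment (SD, n = 2 each, 29 to 52 reads). A further Gria2 coding site at position 80692286 was edited in 29.8 ± 5.05%, 27.9 ± 2.43% and 17.3 ± 2.94% of 78 to 155 reads. In E16.5 brain a coding site of Blcap at position 157558110 on chromosome 2 stood at 8.43 ± 0.14% with IgG and 15.1 ± 2.72% with anti-G3BP1. The Flna coding site at position 74226862 on the X chromosome stood at 41.7 ± 3.20% with IgG and 14.7 ± 8.27% with anti-G3BP1 (38 to 75 reads). These sites were chosen after their values were seen, and differences at single sites were not tested.

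Reads assigned to Adarb1 also varied within groups. They include reads with silent changes in the coding sequence, 157 of 158 at codon 548 in E12.5 brain, so these TPM need not measure the mouse transcript alone. The level was 59.2 to 245 TPM in E12.5 brain, with 126 and 59.2 TPM in the IgG libraries and 90.8 and 245 TPM in the anti-G3BP1 libraries, against 22.7 to 30.2 TPM in E16.5 brain. In the fixed embryo it was 9.04 and 18.4 TPM with anti-G3BP1, 4.07 and 5.27 TPM with IgG, and 3.32 and 3.49 TPM without treatment.

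For E16.5 against E12.5 brain, 1 of the 35 splits of the 8 libraries into 4 and 4 gave as many genes as the real one, which was the real split itself with 10089 genes; the highest of the other splits gave 0. A random split of these libraries thus does not give that count, but table, region and sex could.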
